A study of Homo sapiens with 12 samples.

How the data were processed

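The series measured transcript abundances by RNA sequencing of total RNA in human CD4-positive CD25-negative T cells, which are helper T cells depleted of most regulatory cells. Per the labels, thawed cells were kept for 60 min with no cytokine, with 10 ng/ml IL17A, with 10 ng/ml IL17F, or with both, and then cultured for 48 h with fixed antibodies to CD3 and CD28 at 1 µg/ml each. The samples are described as 3 healthy donors in each of 4 conditions, 12 libraries in all. The sample labels name the fourth condition as IL17A plus IL17F, while the series text gives a combined name that could also mean the heterodimer. It is called IL17A plus IL17F here, after the sample labels.

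The authors deposited 1 table per library with transcript lengths, estimated (expected) counts and TPM, a length-corrected relative abundance. Per the file headers these are the columns of a kallisto abundance table, and the submitters' processing notes name kallisto, bcl2fastq and the GRCh38 build. The versions and the transcript release were not given in the sources used here. The deposited estimated counts carry no normalization between libraries, and the deposited TPM sum to 1000000 in each library. Each table listed 173259 transcripts, and the effective length was the length minus 179 bases for the longer transcripts, so no sequence-bias correction of the lengths was visible.

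Transcripts were joined by identifier to GENCODE release 44 on GRCh38, which matched 155518 transcripts (89.8%). The other 17741 transcripts were left out, and they held 5.67% to 6.60% of the estimated counts of a library. Estimated counts were summed to 34834 genes and rounded. The IL17A gene itself was not analysed here, because no matched transcript carried it. All genes of the Y chromosome and XIST, 440 in number, were left out before any test. Library totals were 20548250 to 24559810 estimated counts, and 19167320 to 22959506 after the sum to genes. A count of 0 in a library allows up to 3 counts, or 0.131 to 0.157 counts per 1000000 (CPM). Such floors cover counting error only, since reads without molecular identifiers are not independent molecules.

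Genes were tested in R 4.3.3 with edgeR 4.0.16, using TMM scaling, the filterByExpr filter, robust dispersions and quasi-likelihood F-tests with legacy quasi-dispersions. All 12 libraries shared 1 fit with 8 residual degrees of freedom, and 15095 genes passed the filter, 13761 of them protein-coding. The 8 contrasts were each cytokine condition against control, the mean of the 3 cytokine conditions against control, the 3 differences between cytokine conditions, and the additivity contrast, which is IL17A plus IL17F minus IL17A minus IL17F plus control. Adjusted p-values are Benjamini-Hochberg values over the tested genes, with a threshold of 0.05. Levels are CPM with their SD over 3 libraries, and fold changes come from the edgeR fit with their standard error on the log2 scale. Limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 were used for the alternatives and summaries. On simulated data with fold changes of 1.5, 2 and 4 the fit recovered 53.7%, 83.6% and 98.5% of the changed genes, with 9 false calls among 14768 genes. Only 67, 67 and 66 genes were changed, in the IL17A group alone, and no difference between persons was simulated. The simulation therefore does not give the error rate of the real contrasts, where far more genes were called.

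The donor number in the labels could pair libraries across conditions, and a fit with that number as a block was planned beside the unblocked one. Pairing was checked by correlating what remained of each library after its condition mean was removed. The correlations were -0.00856 to 0.171 (median 0.055) over 18 pairs of libraries sharing a donor number and -0.148 to 0.0854 over 36 pairs sharing neither label. Sample identity was checked with sex-linked genes and with all-or-none genes, reported as counts only. A gene was counted as all-or-none between libraries when it lay under 0.2 CPM in one and above 5 CPM in the other. Any gene could enter this count, so it takes in large differences in expression as well as genes absent in a person.

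Before the data were examined, 32 gene lists were fixed, covering helper T cell programmes, signalling, metabolism, stress, proliferation and markers of other blood cells. They were tested against all other tested genes with camera in limma, with a preset correlation of 0.01, and again with an estimated correlation, with fry and with the donor block. Genes to be named were fixed at the same time. For each comparison with control and for the mean these were up to 12 genes in each direction by fold change, with a mean of at least 1 CPM, an adjusted p under 0.05 and the same direction in all 3 replicates. For the other contrasts they were up to 3 in each direction. Up to 4 members of each list by smallest p and 16 genes chosen in advance were added, and some genes the rule picked are not reported here. Genes of chromosome 6 from 28 to 34 Mb, pseudogenes and multi-copy families, 1249 of the tested genes, are not named. Some of these genes, though not all, can be present in one person and absent in another or share reads with near-identical copies. Of the tested list members, 26 of 30 NF-kappaB response genes, 17 of 19 Th1 genes and only 3 of 8 markers of gamma-delta T and MAIT cells could still be named. This exclusion was chosen after the data were seen. Of the genes picked by fold change it left 4 of 24 for IL17A, 1 of 24 for IL17F, 6 of 24 for IL17A plus IL17F, 6 of 24 for the mean, and 0 of 6 in each contrast without control. For those contrasts the genes named were picked from the genes already named, after their values were seen.

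Alternatives planned before the data were examined were the donor block, the RLE factors of DESeq2, DESeq2 and limma-voom in place of edgeR, no count filter and a stricter one of 5 CPM, an offset for transcript length, fits on the compared groups alone, edgeR 4 quasi-dispersions, a random donor effect, log2 TPM with pseudocounts of 0.5 and 0.1, and the omission of each replicate or library. Chosen after the data were seen were protein-coding genes alone without the unnamed classes, the estimated correlation together with the donor block for lists, and a correction for GC content and transcript length by a spline with 4 degrees of freedom.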

Results

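RNA abundance was measured in stimulated CD4-positive CD25-negative T cells under 4 conditions with 3 libraries each, namely control, IL17A, IL17F and IL17A plus IL17F. The series asks whether the IL-17 cytokines, made by T helper 17 cells, alter how helper T cells respond to suppression. Libraries held 20548250 to 24559810 estimated counts, with 22454069 to 23399290 in control, 21897695 to 24528586 with IL17A, 22504589 to 23429795 with IL17F and 20548250 to 24559810 with both cytokines. Mitochondrial transcripts took 4.74% ± 0.225 of counts in control, 4.60% ± 0.121 with IL17A, 3.99% ± 0.181 with IL17F and 3.30% ± 0.0889 with both (SD, n = 3). The 50 most abundant genes took 16.9% ± 0.570, 16.4% ± 0.208, 16.3% ± 0.301 and 13.3% ± 0.288 of counts in the same order, and ribosomal protein genes 6.23% ± 0.102, 6.46% ± 0.0252, 6.54% ± 0.192 and 5.54% ± 0.274.

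The libraries of 3 of 3 donor numbers did not match one another in sex-linked genes, while this was so in 0 of 4 condition groups. Genes near 0 in one library and above 5 CPM in the other numbered 1 to 7 (median 4) over 12 pairs sharing a condition label. They numbered 24 to 54 (median 30.5) over 18 pairs sharing a donor number and 22 to 56 (median 31.5) over 36 pairs sharing neither. In these sex-linked and all-or-none genes the libraries were alike by condition and not by donor number. Of 43 genes that were all-or-none between condition groups, 6 lay on chromosome 6 from 28 to 34 Mb and 16 were pseudogenes. Differences in expression between conditions can also enter this count, so the all-or-none genes alone do not tell persons apart. Every difference between conditions given here is a difference between libraries that carry a condition label. The files do not separate the cytokine from the person, and p-values measure only the spread between libraries of one label, which may be technical. The mismatch in sex-linked genes argues against 1 person behind each donor number, so n = 3 counts libraries and not paired donors.

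**Figure D1:**
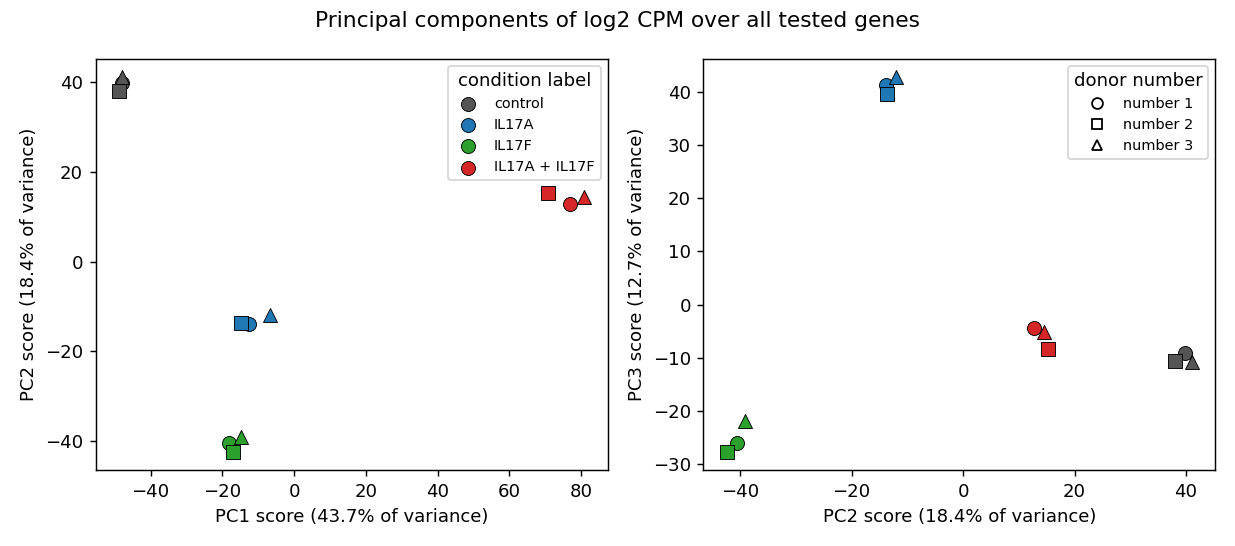
Principal component scores of the 12 libraries from log2 CPM of all tested genes, colour for the condition label and marker for the donor number, with the percentage of variance on each axis. Component 1 held 43.7%, component 2 held 18.4% and component 3 held 12.7% of the variance, and the libraries lie together by condition label.

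Condition labels accounted for 74.5% of the variance of log2 CPM over genes, donor numbers for 7.78% and the remainder for 17.7%. In an exact permutation test over the 576 distinct assignments of condition labels within donor numbers, p was 0.00174, the smallest the design allows, and the next highest share was 65.6%. Libraries alike within a condition label for any reason, the person included, would give this p. It therefore does not bear on the cytokines. Between donor numbers 298 genes differed in edgeR, with 0 genes between numbers 1 and 2, 216 between 1 and 3 and 567 between 2 and 3. DESeq2 gave 612 genes for the joint test. Of the 298 genes called in the joint edgeR test, 216 were lower in number 3 than in number 1 by any amount. This is not the set of 216 genes called between 1 and 3, of which 174 were lower. Those lower in the joint set had a median GC content of 51.8% and a median length of 1963 bases. The 82 that were higher had 55.8% and 3519.5 bases, and genes not called had 47.7% and 3661 bases. The source of the donor number differences was not tested.

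The first comparison asked what differed with IL17A. IL1B, the gene of interleukin-1 beta (ENSG00000125538, GRCh38 chromosome 2, 112829751 to 112836816), stood at 201 ± 38.9 CPM in control and 2.84 ± 0.150 with IL17A (SD, n = 3), 70.8-fold lower. CXCL8, a neutrophil chemokine (ENSG00000169429, chromosome 4, 73740519 to 73743716), went from 329 ± 17.8 to 35.2 ± 4.17 CPM. PTGS2, a prostaglandin synthase, went from 50.1 ± 8.23 to 2.62 ± 0.515. ACOD1, which makes itaconate in activated macrophages, had 9.001 ± 1.55 CPM in control and 0 counts in all 3 IL17A libraries, at least 195-fold lower with a floor of 3 counts over the group. The other genes named by size of decrease were S100A9 (9.69 against 0.0294 CPM), SERPINB2 (5.50 against 0.0147 CPM) and CXCL5 (9.03 against 0.0294 CPM). Only 4 of the 24 genes picked by fold change with IL17A could be named, and the rest belong to the unnamed classes.

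Interferon response genes were higher with IL17A, with 27 of 29 tested type I interferon genes higher and 0 lower (28 higher adjusted over the list alone; camera adjusted p = 7.42e-16, and adjusted p = 0.395 with an estimated correlation). Among them IFIT2 rose 4.67-fold and MX2, an antiviral GTPase, from 13.3 ± 1.33 to 44.7 ± 7.58 CPM. The IL-17 response genes known from epithelium and fibroblasts fell, with 15 of 22 lower and 0 higher (16 lower adjusted over the list alone; camera adjusted p = 2.97e-13, and adjusted p = 0.00668 with an estimated correlation). Monocyte markers fell in 7 of 10 and rose in 0 (7 lower and 1 higher adjusted over the list alone; camera adjusted p = 6.26e-06, and adjusted p = 0.0471 with an estimated correlation), including LYZ, the lysozyme gene, from 116 ± 16.3 to 20.8 ± 2.73 CPM. With an estimated correlation and the donor block together, the adjusted p was 0.0324 for the IL-17 response genes and 0.068 for monocyte markers. Of the 22 IL-17 response genes 10 also belong to another list, as do 2 of the 10 monocyte markers. The fall of the IL-17 response genes was not separated from that of the monocyte markers. NK cell markers fell in 8 of 12 and rose in 1 (camera adjusted p = 0.0107, and adjusted p = 0.395 with an estimated correlation).

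Mitotic genes of the G2 and M phases fell in 17 of 25 with IL17A, AURKA among them at 1.48-fold (camera adjusted p = 3.09e-07, and adjusted p = 0.433 with an estimated correlation). S phase genes fell in 6 of 25 (camera adjusted p = 0.0404, and adjusted p = 0.663 with an estimated correlation) and oxidative phosphorylation genes in 12 of 30 (camera adjusted p = 0.000109, and adjusted p = 0.433 with an estimated correlation). Naive and central memory genes rose in 10 of 20 and fell in 3 (camera adjusted p = 0.000912, and adjusted p = 0.433 with an estimated correlation), with LEF1, a transcription factor of naive T cells, going from 93.7 ± 1.40 to 180 ± 14.6 CPM. Apoptosis and survival genes rose in 13 of 25 and fell in 2 (camera adjusted p = 0.000912, and adjusted p = 0.285 with an estimated correlation), with the death receptor gene TNFRSF10B 1.99-fold higher and BBC3, which promotes apoptosis, 2.89-fold higher. T cell activation genes rose in 12 of 28 and fell in 5 (camera adjusted p = 0.0288, and adjusted p = 0.433 with an estimated correlation). Integrated stress response genes rose in 9 of 20 and fell in 2 (camera adjusted p = 0.0434, and adjusted p = 0.433 with an estimated correlation). Heat shock genes were called lower, with 10 of 19 lower and 2 higher (camera adjusted p = 0.0288, and adjusted p = 0.563 with an estimated correlation), although the mean log2 change of the list was 0.37 and its median -0.27. The S phase and heat shock calls ended under the GC and length correction.

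Of the genes chosen in advance, IL17F, itself a Th17 cytokine gene, fell from 34.4 ± 1.69 to 8.41 ± 0.595 CPM with IL17A. IL2RA, the gene of CD25 (ENSG00000134460, chromosome 10, 6010689 to 6062370), fell 1.95-fold, IFNG 1.64-fold, CTLA4 1.99-fold and ZC3H12A 1.16-fold, whereas IL17RA rose 1.74-fold and IL2 1.55-fold. FOXP3 (adjusted p = 0.25), IL10 (adjusted p = 0.914), PDCD1 (adjusted p = 0.613), CD274 (adjusted p = 0.964), NFKBIZ (adjusted p = 0.201) and IL17RC (adjusted p = 0.395) did not pass in edgeR. MKI67 did not pass either (adjusted p = 0.0573), and passed with the donor block (adjusted p = 0.010). In all, 4621 of 15095 genes (30.6%) differed between IL17A and control libraries in edgeR, 2327 higher and 2294 lower, and 461 and 375 of them by more than 2-fold. An offset for transcript length lowered the count to 2929, and leaving out replicate 1 lowered it to 2298.

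**Figure D2:**
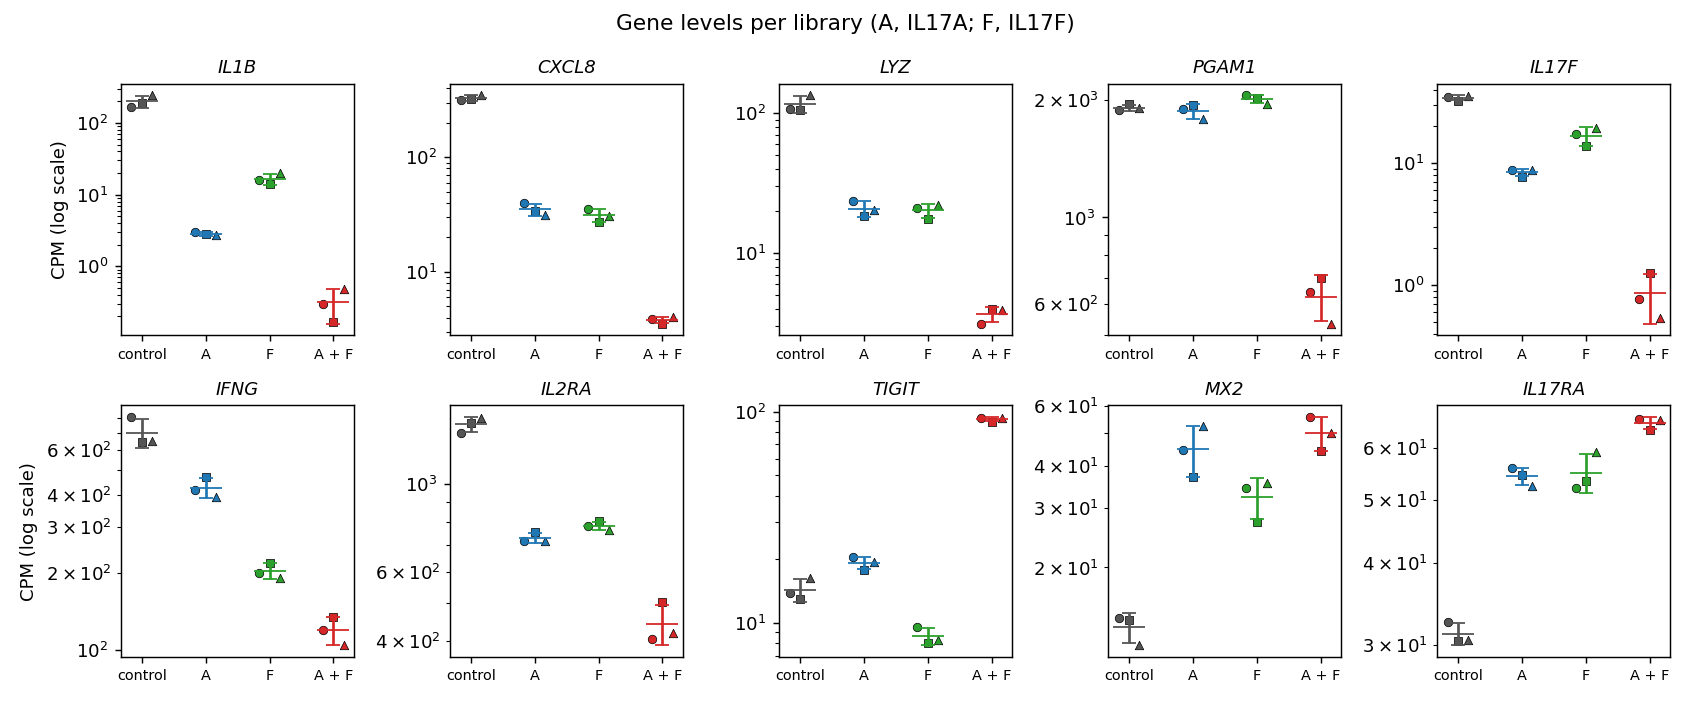
CPM on a log scale of named genes in each library of the 4 condition labels, with points for libraries (marker for the donor number) and bars for the mean ± SD. IL1B stood at 201 CPM in control, 2.84 with IL17A, 16.7 with IL17F and 0.318 with both, and TIGIT at 14.4, 19.2, 8.62 and 92.3 CPM.

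The second comparison asked what differed with IL17F. GNLY, the gene of the granule protein granulysin (ENSG00000115523, chromosome 2, 85685175 to 85698852), went from 280 ± 9.94 to 27.98 ± 4.26 CPM (SD, n = 3), 9.99-fold lower. PRF1, the gene of perforin, fell 3.48-fold. IFNG, the gene of interferon gamma (ENSG00000111537, chromosome 12, 68154768 to 68159740), fell from 700 ± 91.9 to 203 ± 14.1 CPM. EOMES, a transcription factor of cytotoxic cells, fell 12.9-fold. Cytotoxic genes fell in 11 of 15 and rose in 0 (camera adjusted p = 3.62e-08, and adjusted p = 0.0322 with an estimated correlation), and Th1 genes fell in 13 of 19 and rose in 2 (14 lower adjusted over the list alone; camera adjusted p = 6.43e-05, and adjusted p = 0.0322 with an estimated correlation).

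Markers of NK cells fell in 10 of 12 with IL17F and rose in 1, with FCGR3A 35.5-fold lower (camera adjusted p = 3.40e-07, and adjusted p = 0.0322 with an estimated correlation). Markers of CD8 T cells fell in 4 of 5 (camera adjusted p = 0.00101, and adjusted p = 0.0322 with an estimated correlation), and those of gamma-delta T and MAIT cells in 6 of 8 (camera adjusted p = 4.28e-05, and adjusted p = 0.0974 with an estimated correlation). Only 3 of the 8 gamma-delta T and MAIT markers lie outside the classes that are not named. Monocyte markers fell in 7 of 10 (camera adjusted p = 6.43e-05, and adjusted p = 0.0322 with an estimated correlation), LYZ to 20.3 ± 2.33 CPM. The IL-17 response genes fell in 17 of 22 and rose in 1 (camera adjusted p = 3.56e-12, and adjusted p = 0.00898 with an estimated correlation), with CXCL8 10.5-fold lower. With an estimated correlation and the donor block together the IL-17 response genes passed (adjusted p = 0.0399), and the other lists did not (adjusted p = 0.0847 for Th1 genes and CD8 markers and 0.0626 for cytotoxic genes, monocyte and NK cell markers). These lists overlap, as 8 of 15 cytotoxic genes, 5 of 11 NK cell markers and 3 of 5 CD8 markers, counted without genes that are not named, also belong to another list. CXCL5, the gene named by size of decrease, had 9.03 ± 1.74 CPM in control and 0 counts with IL17F, at least 190-fold lower with a floor of 3 counts over the group.

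Type I interferon genes rose in 26 of 29 and fell in 0 with IL17F (29 higher adjusted over the list alone; camera adjusted p = 6.85e-13, and adjusted p = 0.249 with an estimated correlation). Integrated stress response genes rose in 10 of 20 and fell in 2 (camera adjusted p = 0.000312, and adjusted p = 0.155 with an estimated correlation). Among them CTH, which makes cysteine (ENSG00000116761, chromosome 1, 70411218 to 70439851), rose from 3.57 ± 0.330 to 32.9 ± 3.89 CPM, the asparagine synthetase gene ASNS 2.32-fold and the serine synthesis gene PHGDH 2.16-fold. Apoptosis and survival genes rose in 8 of 25 and fell in 1 (camera adjusted p = 0.00356, and adjusted p = 0.152 with an estimated correlation). T cell activation genes rose in 17 of 28 and fell in 4 (camera adjusted p = 0.00869, and adjusted p = 0.325 with an estimated correlation). Glycolysis and hypoxia genes rose in 6 of 30 and fell in 1 (camera adjusted p = 0.0129, and adjusted p = 0.612 with an estimated correlation), and naive and central memory genes rose in 12 of 20 and fell in 5 (camera adjusted p = 0.0162, and adjusted p = 0.473 with an estimated correlation).

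Smaller list decreases with IL17F covered Th17 genes (11 of 18 lower, 4 higher; camera adjusted p = 0.0129, and adjusted p = 0.152 with an estimated correlation) and regulatory T cell genes (8 of 20 lower, 1 higher; camera adjusted p = 0.0121, and adjusted p = 0.152 with an estimated correlation). They also covered oxidative phosphorylation genes (6 of 30 lower, 0 higher; camera adjusted p = 0.0162, and adjusted p = 0.576 with an estimated correlation) and IL-2 and STAT5 response genes (11 of 22 lower, 3 higher; camera adjusted p = 0.0309, and adjusted p = 0.473 with an estimated correlation). Cholesterol synthesis genes were lower in 10 of 24 and higher in 2 (camera adjusted p = 0.0368, and adjusted p = 0.473 with an estimated correlation). Th2 genes were lower in 5 of 14 (camera adjusted p = 0.0371, adjusted p = 0.167 with an estimated correlation, and adjusted p = 0.0991 with the donor block). The GC and length correction ended the calls of oxidative phosphorylation, IL-2 and STAT5 response, cholesterol synthesis and Th2 genes.

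The IL17F gene fell 2.05-fold with IL17F, IL2RA 1.81-fold, CTLA4 1.66-fold and ZC3H12A 1.26-fold, and IL17RA rose 1.76-fold and IL2 1.46-fold. FOXP3 missed the threshold in edgeR (adjusted p = 0.0733) and was lower with the donor block (adjusted p = 0.00597). IL10 (adjusted p = 0.0521), PDCD1 (adjusted p = 0.574), CD274 (adjusted p = 0.608), MKI67 (adjusted p = 0.162), NFKBIZ (adjusted p = 0.158) and IL17RC (adjusted p = 0.887) did not pass. In edgeR 4992 genes (33.1%) differed, 2601 higher and 2391 lower, with 508 and 525 of them beyond 2-fold, and 2912 differed without replicate 1.

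The third comparison asked what differed with IL17A plus IL17F. PGAM1, a glycolytic mutase (ENSG00000171314, chromosome 10, 97426191 to 97433444), went from 1910 ± 33.1 to 627 ± 84.7 CPM (SD, n = 3). SCD, which desaturates fatty acids, went from 1129 ± 52.2 to 288 ± 22.2. TIGIT, an inhibitory receptor (ENSG00000181847, chromosome 3, 114276913 to 114310288), rose from 14.4 ± 1.76 to 92.3 ± 2.32 CPM. LRRN3, expressed in naive T cells (ENSG00000173114, chromosome 7, 111091006 to 111125454), rose from 23.8 ± 2.28 to 226 ± 11.3. HAVCR2, the gene of the inhibitory receptor TIM-3, fell 7.13-fold.

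Glycolysis and hypoxia genes fell in 28 of 30 with both cytokines and rose in 1 (camera adjusted p = 7.40e-09, and adjusted p = 0.316 with an estimated correlation). G2 and M phase genes fell in 24 of 25 (camera adjusted p = 3.20e-08, and adjusted p = 0.316 with an estimated correlation) and S phase genes in 22 of 25 (camera adjusted p = 1.68e-06, and adjusted p = 0.316 with an estimated correlation). Oxidative phosphorylation genes fell in 26 of 30 (camera adjusted p = 5.94e-06, and adjusted p = 0.316 with an estimated correlation) and cholesterol synthesis genes in 19 of 24, with 1 higher (camera adjusted p = 6.08e-06, and adjusted p = 0.246 with an estimated correlation). IL-2 and STAT5 response genes fell in 13 of 22 and rose in 4 (camera adjusted p = 0.00562, and adjusted p = 0.316 with an estimated correlation). Type I interferon genes rose in 23 of 29 and fell in 0, MX2 to 49.96 ± 5.78 CPM (camera adjusted p = 8.13e-06, and adjusted p = 0.428 with an estimated correlation). Apoptosis and survival genes rose in 17 of 25 and fell in 4, TNFRSF10B by 4.44-fold (camera adjusted p = 0.00808, and adjusted p = 0.311 with an estimated correlation). Naive and central memory genes rose in 13 of 20 and fell in 7 (camera adjusted p = 0.0186, and adjusted p = 0.428 with an estimated correlation).

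The IL-17 response genes fell in 16 of 22 with both cytokines and rose in 1, with CXCL8 86.4-fold lower at 3.81 ± 0.249 CPM (camera adjusted p = 1.86e-06, and adjusted p = 0.0816 with an estimated correlation). Th17 genes fell in 12 of 18 and rose in 4, with CXCL13, a B cell chemokine, going from 24.6 ± 2.56 to 2.04 ± 0.0394 CPM (camera adjusted p = 0.00562, and adjusted p = 0.246 with an estimated correlation). Cytotoxic genes fell in 11 of 15 and rose in 2 (camera adjusted p = 0.002, and adjusted p = 0.246 with an estimated correlation). Markers of monocytes fell in 8 of 10, LYZ to 3.66 ± 0.463 CPM (camera adjusted p = 6.09e-05, and adjusted p = 0.0983 with an estimated correlation). Markers of NK cells fell in 8 of 12 and rose in 3 (camera adjusted p = 0.00562, and adjusted p = 0.311 with an estimated correlation). Of the genes named by size, MGAT5B stood at 10.3 ± 2.17 CPM against 0.0466 in control, IL1B at 0.318 ± 0.159, SERPINB7 at 0.0143 against 13.3 and CXCL5 at 0.0141 against 9.03. CXCL1 and ACOD1 had 0 counts, at least 232-fold and 204-fold lower with a floor of 3 counts over the group.

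IL2RA fell 3.22-fold with both cytokines, IFNG 5.86-fold, IL10 7.07-fold, IL2 2.62-fold, CTLA4 3.45-fold, PDCD1 1.57-fold, CD274 1.80-fold, MKI67 1.36-fold and IL17F 39.4-fold, while IL17RA rose 2.10-fold and NFKBIZ 1.14-fold. FOXP3 missed the threshold (adjusted p = 0.0595) and was lower with the donor block (adjusted p = 0.00538). IL17RC (adjusted p = 0.641) and ZC3H12A (adjusted p = 0.197) did not pass. In edgeR 9463 genes (62.7%) differed, 4772 higher and 4691 lower, with 1609 and 1249 of them beyond 2-fold.

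**Figure D3:**
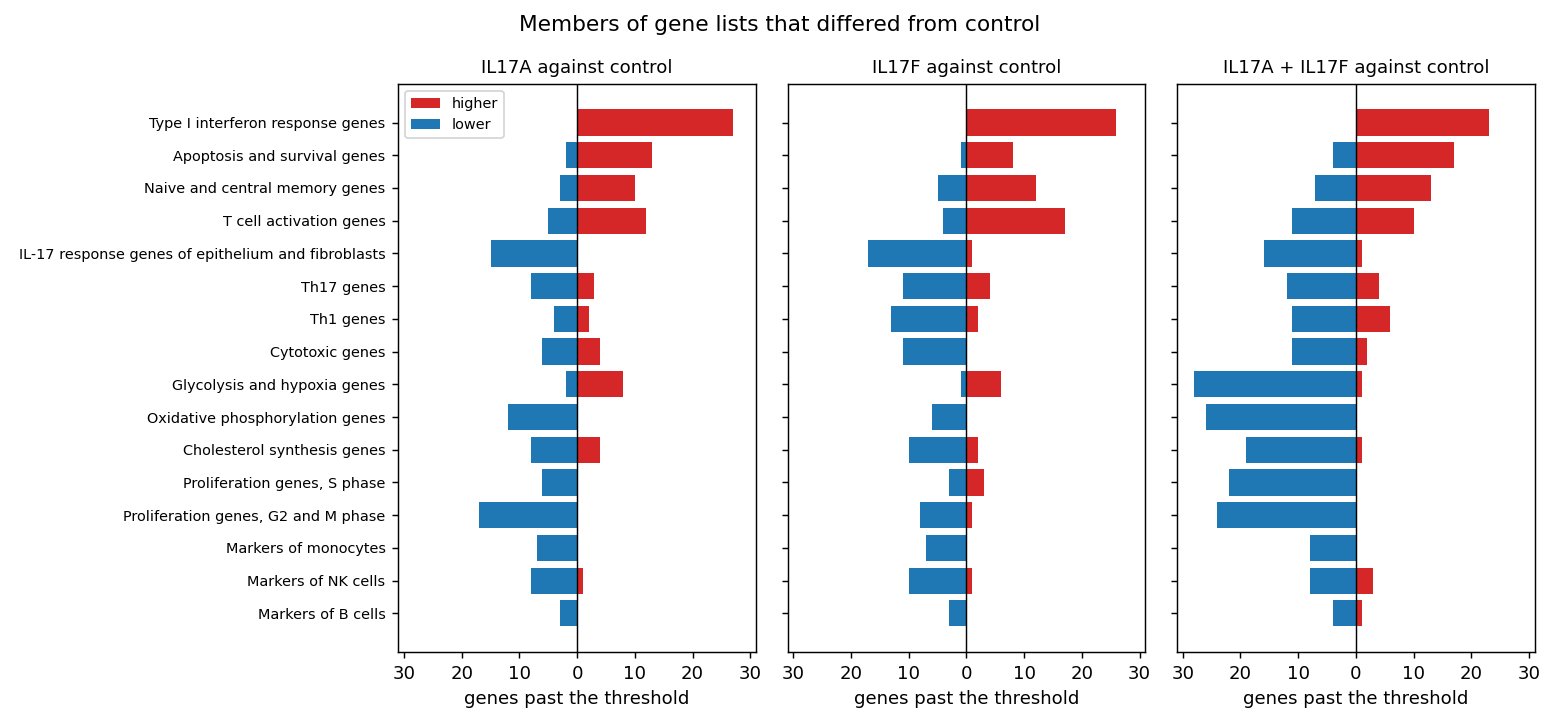
Members of 16 gene lists that were higher (right) or lower (left) than control at an adjusted p under 0.05, as counts of genes, for each cytokine condition. Type I interferon genes were higher in 27, 26 and 23 of 29, and glycolysis and hypoxia genes were lower in 2, 1 and 28 of 30.

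The remaining lists, of which that of inhibitory receptors also holds ligands, were not called. With IL17A these were IL-17 receptor and adaptor genes, Th17, Th1, Th2, follicular helper and regulatory T cell genes, inhibitory receptors, TGF-beta, IL-10 and adenosine response, anergy and TCR inhibitor, IL-2 and STAT5 and NF-kappaB response, glycolysis and hypoxia, cholesterol synthesis and cytotoxic genes, and markers of B cells, dendritic cells, CD8 T cells, gamma-delta T and MAIT cells, platelets and red cells (camera adjusted p 0.0543 to 0.902). Of these, inhibitory receptors were called higher with the donor block (adjusted p = 0.032, and adjusted p = 0.33 with the block and an estimated correlation) and under the GC and length correction. With IL17F they were IL-17 receptor and adaptor genes, follicular helper genes, inhibitory receptors, TGF-beta, IL-10 and adenosine response, anergy and TCR inhibitor, NF-kappaB response, S phase, G2 and M phase and heat shock genes, and markers of B cells, dendritic cells, platelets and red cells (camera adjusted p 0.129 to 0.873). With both cytokines they were IL-17 receptor and adaptor, Th1, Th2, follicular helper and regulatory T cell genes, inhibitory receptors, TGF-beta, IL-10 and adenosine response, T cell activation, anergy and TCR inhibitor, NF-kappaB response, integrated stress response and heat shock genes, and markers of B cells, dendritic cells, CD8 T cells, gamma-delta T and MAIT cells, platelets and red cells (camera adjusted p 0.0519 to 0.885). Adjusted over the list alone, counts were the same as over all genes in 15 of 32 lists with IL17A, 18 with IL17F and 28 with both, and differed by at most 3 genes in a direction.

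Averaged over the 3 cytokine conditions, 7502 genes (49.7%) differed from control in edgeR, 3727 higher and 3775 lower. The genes named by size were all lower, namely ACOD1, CXCL5, CXCL1, SERPINB2, S100A9 and SERPINB7, each between 5.50 and 13.3 CPM in control and under 0.5 CPM in each cytokine condition (highest 0.45 CPM, SERPINB7 with IL17A).

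Lists were not tested between cytokine conditions. GNLY was 7.68-fold lower with IL17F than with IL17A, PRF1 2.96-fold lower, IFNG 2.11-fold lower and TIGIT 2.23-fold lower, while CTH was 4.30-fold and IL1B 5.87-fold higher (edgeR adjusted p = 2.22e-09, 7.37e-08, 2.25e-05, 9.48e-07, 1.88e-07 and 8.07e-06). In all 2790 genes (18.5%) differed, 1443 higher and 1347 lower with IL17F. The count was 1737 with the transcript length offset, 838 without replicate 1, and 1744 without either replicate 1 of IL17A or replicate 2 of IL17F.

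Against IL17A, TIGIT was 4.80-fold and LRRN3 5.25-fold higher and PGAM1 2.99-fold, SCD 3.17-fold and IL10 7.19-fold lower with both cytokines. In that contrast 8131 genes (53.9%) differed, 4131 higher and 4000 lower. Against IL17F, TIGIT was 10.7-fold and LRRN3 6.92-fold higher and PGAM1 3.20-fold, SCD 3.54-fold and IL10 9.05-fold lower. Here 8573 genes (56.8%) differed, 4410 higher and 4163 lower. In the additivity contrast LRRN3 stood 3.83-fold above and PGAM1 3.14-fold, IL10 9.20-fold, IL2 5.91-fold and CTH 11.9-fold below the sum of the separate changes on the log2 scale. IFNG did not differ from that sum by an amount that passed (adjusted p = 0.809). In edgeR 6036 genes (40.0%) passed in this contrast, 3081 above and 2955 below the sum, and 3754 passed without replicate 1.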

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

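The tests of library matching, of marker lists against one another, of the protein-coding restriction and of the GC and length correction were chosen after the results were seen, while the contrasts and the other splits of the libraries were planned. In the additivity contrast 6036 genes passed, so the difference of IL17F-labelled libraries from their comparison libraries was not the same without and with the IL17A label. The contrast reads as such only if the fourth condition was the 2 cytokines added together, and it carries the same possible mixture of person and cytokine as the others. Transcripts without a gene match, which no comparison used, took 6.34% ± 0.112 of counts with IL17A and 6.56% ± 0.0666 with both cytokines, above each control library (5.79% ± 0.151, SD, n = 3).

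The first pattern is that libraries were alike by condition label and not by donor number in sex-linked and all-or-none genes, although 298 genes differed between donor numbers. Numbers 1 and 2 differed in 0 genes. The genes called differed in GC content from the others, yet 237 genes still differed after the GC and length correction. The source of these differences was not tested, so the 298 genes do not show that a donor number marks a person. Chance division of reads between near-identical gene copies is argued against, since the highest number of all-or-none genes between libraries sharing a condition was 7 and the lowest between libraries sharing a donor number was 24. Another person behind each condition label may be the source, since 3 of 3 donor numbers and 0 of 4 condition groups held libraries that did not match in sex-linked genes. Of the 24 genes picked by fold change against control, 7 with IL17A, 4 with IL17F and 6 with both lay in the chromosome 6 region. Pseudogenes elsewhere numbered 8, 13 and 8, and other multi-copy genes 5, 6 and 4. Some of these genes, though not all, can be absent in a person or share reads, so the largest differences do not separate person from cytokine. A response to the cytokines as the source of the other gene differences stays open: 8920 protein-coding genes still differed between IL17A plus IL17F and control without the chromosome 6 region and multi-copy families, but person and cytokine may have changed together. These labels do not let the 2 be told apart.

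The second pattern is that most monocyte and NK cell markers were lower in the cytokine libraries, although 3 NK cell markers (CD160, XCL1 and XCL2) and 2 of 5 CD8 T cell markers were higher with both cytokines. Fewer monocytes in the cytokine cultures stays open for the monocyte part. Of the 30 marker tests over the 3 comparisons, 22 were lower and 0 higher. These counts are the pattern itself, from 10 markers against the same control libraries, so they cannot test this explanation. Exceptions were CD163 and CD36, which did not pass in any of the 3 (adjusted over the list alone, 1 marker was higher with IL17A), and VCAN, which did not pass with either cytokine alone, and 2 of the 10 markers also belong to the IL-17 response list. LYZ stood at 116 CPM and S100A9 at 9.69 CPM in control, and the isolation of CD4-positive CD25-negative cells is meant to remove monocytes. Most IL-17 response genes were lower in the same 3 comparisons, and whether they and the monocyte markers fell from the same source was not tested. A purer T cell population in general cannot be told apart from fewer monocytes with so few markers, as the smallest adjusted permutation p of a difference from NK or B cell markers was 0.356 over 6 comparisons, nor can a cytokine response of the cells present, as 8 of 12 NK cell markers were lower with both cytokines while person and cytokine may have changed together.

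The third pattern is that most genes differed in the libraries labelled with both cytokines, whose 50 most abundant genes also took less of the counts (13.3% against 16.9% in control). A few genes taking most of the counts is argued against as the whole cause. The 50 most abundant genes took 13.03% to 17.51% of counts in any library, while 1609 genes were higher and 1249 lower by more than 2-fold. The RLE factors tried for it gave 9478 genes but moved almost nothing, and that test was dropped as deciding nothing. GC content or transcript length bias as the whole cause is argued against, since 9465 genes differed after the correction against 9463 before it, 8510 of them shared, while the same correction lowered the genes that differed between donor numbers from 298 to 237. A response to the cytokines stays open here too, for the reason given with the first pattern.

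For contrasts of 3 against 3 libraries the 10 splits were too few for a share under 0.05. The real split gave 4982 genes for IL17A against control (highest other 1), 4833 for IL17F (highest other 1), 9297 for both cytokines (highest other 0), 2404 for IL17F against IL17A (highest other 0), 7767 for both against IL17A (highest other 0) and 8084 for both against IL17F (highest other 0). Of 100 splits each, 1 was as large as the real one, the real one itself, for the mean of the cytokine conditions (2063 genes in a fit with 2 groups, highest other 75), for additivity (6036, highest other 5161) and for donor numbers (298, highest other 218). Donor numbers were shuffled within conditions, so chance is argued against for them as far as libraries of one condition are interchangeable. For the mean and additivity the splits mix libraries of unlike conditions, which widens the spread within groups, so the first rank of the real split decides nothing. Libraries of one condition label were alike, so these splits do not exclude chance differences between persons.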

How the results depend on the processing

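The corrections for GC content and length, the restriction to protein-coding genes and the estimated correlation together with the donor block were added after the data were seen, and all other alternatives were planned. Over 507 pairs of a named gene and a comparison, 11784 alternative values kept their direction and side of the threshold, 323 fell short of it, 83 passed newly and 6 reversed. Of the list tests 1048 stayed on their side, 117 fell short and 71 passed newly. No scaling moved the median of all genes by more than 0.1 on the log2 scale, and RLE factors gave 9478 genes for both cytokines against control. The donor block gave 5422 genes for IL17A, 5731 for IL17F, 9817 for both and 3560 for IL17F against IL17A.

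An offset for transcript length gave 2929 genes for IL17A against control and 1737 for IL17F against IL17A, and 3443 and 2147 together with the block. DESeq2 gave 612 genes between donor numbers. Lists past the threshold numbered 2 with IL17A, 6 with IL17F and 0 with both under an estimated correlation, and 1, 1 and 0 with the donor block as well. The GC and length correction gave 11, 15 and 14 lists against 12, 19 and 14. Fry, which asks another question, gave 21 with IL17A and 28 with both, and 20 and 30 with the block. The log2 change of PFKP with IL17F was -0.054 with the length offset. That of MKI67 with IL17F was -0.28 with the length offset and -0.21 in log2 TPM with either pseudocount and the block, and that of ITGA2B with both cytokines was 0.10 and 0.12 in log2 TPM with the block. The cause was not tested for these.

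Leaving out a replicate or a library gave 2298 to 4140 genes for IL17A against control, 2912 to 4503 for IL17F, 7818 to 9345 for both, 5468 to 7770 for the mean, 838 to 2663 for IL17F against IL17A, 6010 to 7966 for both against IL17A, 6589 to 8443 for both against IL17F and 3754 to 6108 for additivity, with fewer libraries in each fit. With the block the ranges were 2980 to 4694, 3743 to 4706, 8411 to 9218, 6161 to 7352, 1861 to 2438, 7114 to 7749, 7610 to 8332 and 4920 to 5710. Of single libraries, replicate 1 of IL17A and replicate 2 of IL17F each took IL17F against IL17A to 1744. Depth limits genes at 0 counts, where a library of this size allows up to 0.157 CPM.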

Other observations

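Further members of the lists, described here after their values were seen, moved with the combination of cytokines. SMAD3, a transducer of TGF-beta signals, stood at 36.2 ± 2.59 CPM in control, 89.7 ± 10.3 with IL17A, 62.3 ± 5.10 with IL17F and 179 ± 20.1 with both (SD, n = 3), 4.95-fold higher with both (edgeR adjusted p = 1.94e-10). TGFBR2, a receptor of TGF-beta, went from 116 ± 2.61 to 191 ± 18.9 CPM and IL10RA, a receptor chain of interleukin-10, from 56.0 ± 3.95 to 126 ± 6.36 with both. The list of TGF-beta, IL-10 and adenosine response genes was not called, with 13 of 23 members higher and 6 lower (camera adjusted p = 0.09). Heat shock genes were lower in 12 of 19 and higher in 4 with both cytokines (camera adjusted p = 0.0586), although HSPA6 rose 13.4-fold. Integrated stress response genes were higher in 9 of 20 and lower in 6 (camera adjusted p = 0.591), with PPP1R15A 4.76-fold higher and SLC7A11, a cystine transporter, 5.97-fold lower.

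Inhibitory receptors and their ligands did not move together with both cytokines. CD96 rose 3.12-fold, CD5 2.27-fold and TIGIT 6.42-fold, while HAVCR2 fell 7.13-fold and the ligand gene CD274 1.80-fold. Of the 20 members 9 were higher and 7 lower (camera adjusted p = 0.591). Of the Th2 genes, IL4R rose 2.57-fold, IL13 3.58-fold and GATA3 1.87-fold with both cytokines, in a list with 8 of 14 members higher and 1 lower that was not called (camera adjusted p = 0.144).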
